A study of Mus musculus with 16 samples.

How the data were processed

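Messenger RNA levels were measured on 16 Affymetrix Mouse Gene 1.0 ST arrays, each hybridised with RNA from 1 pool of bone marrow cells of C57BL/6J mice. LSK cells (lineage-negative, Sca1-positive, c-Kit-positive) hold the haematopoietic stem cells and the earliest progenitors, and MP cells (lineage-negative, Sca1-negative, c-Kit-positive) are myeloid progenitors. Both populations came from wild-type (WT) mice and from mice without the DNA damage sensor Parp-2 (Parp-2-/-), either unirradiated or 2.5 hours after 5 Gy of gamma radiation. The 8 groups held 2 pools each, every pool came from at least 3 mice, and the pools were treated as separate samples.

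The deposited values are log2 intensities of transcript clusters made by robust multi-array averaging (RMA). The submitters' processing notes name RMA, limma, affy 2.10 and R 2.15, without the role or order of each. The log base and the set of arrays normalised together are not given in the sources used here. The log2 scale was read from the values, whose medians lay between 4.74 and 4.92 on the 16 arrays, with minima of 1.12 to 1.42 and maxima of 13.12 to 13.37. The values were used as deposited, with no further scaling. The small number of arrays limits the precision: the median standard error was 0.207 log2 units for a difference between a pair of groups and 0.292 for an interaction.

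The table held 34760 rows. Of these, 21640 carried 1 gene symbol (19937 distinct symbols), 1321 carried several and 11799 carried none. The 22961 rows with at least 1 symbol were tested. Symbols were matched to the RefSeq annotation of assembly GRCm38.p6 by Entrez identifier for 21553 rows, and 0 had to be updated. No gene is named from a row with several symbols.

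Comparisons were made in limma 3.58.1 under R 4.3.3, with a linear model of 8 group means over all 16 arrays, moderated variances (eBayes; 8 residual and 4.35 prior degrees of freedom) and two-sided tests. The p-values were adjusted by the Benjamini-Hochberg method over the tested rows within each comparison, and a row was called at an adjusted p under 0.05. There were 12 comparisons: the radiation response in each of the 4 combinations of genotype and cell type, the genotype difference in each of the 4 combinations of cell type and irradiation state, the genotype by irradiation interaction in each cell type, unirradiated WT LSK against MP cells, and the cell type by irradiation interaction in WT. Changes are given in log2 units ± standard error with n = 2 pools per group unless stated otherwise. A level below the median of its array is not shown to be above background. Where this holds for every array of 1 group, the size of a difference is a lower bound: among 188 called named-gene results between a pair of groups, 39 had 1 such group, and 2 had both, where the size is not measured. The table of named genes was checked for this after the values were seen.

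Gene groups were tested as 31 fixed lists of 700 genes, of which 617 matched a row, 4 of them through an older symbol. A list had 2 to 37 measured members, and each gene was represented by its row with the highest mean. The lists covered p53 targets (arrest and feedback; apoptosis), the BCL2 family (pro-survival with inhibitors of apoptosis; pro-apoptotic outside the p53 list), mitosis and G2/M, DNA replication and S phase, double-strand break repair and checkpoint, base excision repair and the PARP family, nucleotide excision repair, Fanconi anaemia, NF-kappaB and inflammatory genes, interferon-stimulated genes, immediate early genes, antioxidant NRF2 targets, unfolded protein and amino acid stress (ATF4), heat shock, cytoplasmic ribosomal proteins, mitochondrially encoded genes and the genes near Parp2 on chromosome 14. The marker lists covered haematopoietic stem cells, lymphoid priming, granulocyte and monocyte progenitors, erythroid cells, megakaryocytes and platelets, B lymphocytes, T and NK cells, mature neutrophils, macrophages, mast cells and basophils, dendritic cells, and endothelial and stromal cells. Each list was tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists within a comparison. Members were counted at an adjusted p under 0.05 over all tested rows and, separately, adjusted over the list alone.

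Named genes followed a rule. Parp2 and Parp1 are reported in every comparison. The 8 largest rises and 8 largest falls were taken among called rows with 1 symbol in which every array of a group lay above every array of the other. Predicted genes, small RNA genes and multi-copy receptor families were skipped. Up to 4 members of each list with the largest absolute change were added. A pair of further genes fixed with Parp2 and Parp1 are not reported, 1 of them because its row carries 2 symbols and the other because it was not on a tested row. Not every gene taken by the rule is printed. Any gene named outside the rule is said to have been chosen after its values were seen.

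The groups, comparisons, tests, lists, named-gene rule and most alternatives were fixed before the data were examined. The alternatives were the pool number as a block, only the 8 arrays of the cell type, only the 4 arrays of the groups compared, no rows among the 30% dimmest, all rows with or without a gene, eBayes with trend and robust, a further quantile normalisation, 1 value per gene, a change of at least 1.5-fold, and each array left out in turn. A fit without 1 array leaves 1 array in its group, so the spread comes from the other groups. Its counts show only how far a result hangs on single arrays. For the lists, camera with an estimated correlation and fry were also run. Added after the values were seen were the fit to the 8 arrays of a cell type for named genes and lists, a variance weight for each cell type, the genotype difference averaged over both irradiation states (a model of genotype and irradiation fitted to the 8 arrays of a cell type), its comparison between cell types (from the 16-array model), and the tests of explanations in the closing section, the splits of arrays included.

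The procedure was tested on simulated data, with 100 genes changed by 1 log2 unit and 100 by 2 in each of 4 comparisons. For the radiation response of WT LSK cells, the fit to 16 arrays recovered 55% of the smaller and 89% of the larger changes, and 37.7% of its 231 calls were false. The fit to the 8 LSK arrays recovered 6% and 64%, with 2.8% false. For the radiation response of WT MP cells the fit to 16 arrays recovered 53% and 96%, with 3.9% false, and the fit to the 8 MP arrays 64% and 93%, with 3.1% false. For the unirradiated genotype difference in LSK cells, 39.2% of the calls of the fit to 16 arrays were false, against 2.4% in the fit to 8. In MP cells these shares were 4.8% and 4.3%. Each simulated row had the LSK and MP spread estimated from its few residuals, so sampling error there entered as a true difference in spread. The false shares also depend on the number of genes changed, so they are not error rates of the calls in this report. Because the shares differed between the fits, counts from both stand side by side in the report.

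Differences that need raw intensity files, such as the signal of single probes within a transcript cluster, were not analysed here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.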

Results

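The series asks how haematopoietic stem and progenitor cells of WT and Parp-2-/- mice differ in gene expression, before and 2.5 hours after 5 Gy of gamma radiation. The targeted gene was examined first, since it checks the genotype labels. Parp2 read 5.70 to 6.77 on the 4 Parp-2-/- LSK arrays against 7.40 to 7.96 on the 4 WT LSK arrays, and 6.74 to 7.11 against 7.98 to 8.40 in MP cells. Every Parp-2-/- array therefore lay below every WT array of its cell type. Over all 16 arrays the mean difference within cell type and irradiation state was -1.43 log2 units (exact two-sided stratified permutation test, p = 0.00154, the smallest value that its 1296 arrangements allow). The probe set averages probes along the transcript and may cover parts outside the deleted part, so a residual signal does not measure remaining protein.

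In the separate comparisons the Parp2 differences did not pass after adjustment. They were -1.40 ± 0.26 in unirradiated LSK cells (adjusted p = 0.11), -1.26 ± 0.26 in unirradiated MP cells (adjusted p = 1), -1.44 ± 0.26 in irradiated LSK cells (adjusted p = 0.1) and -1.62 ± 0.26 in irradiated MP cells (adjusted p = 0.23). Parp1, which encodes the main nuclear poly(ADP-ribose) polymerase, differed by -0.21 ± 0.15, 0.19 ± 0.15, -0.51 ± 0.15 and 0.06 ± 0.15 in the same order (adjusted p = 0.72, 1, 0.32 and 1).

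The comparison of unirradiated WT LSK with WT MP cells checks the sort. LSK cells had 11.7-fold more Dntt (3.55 ± 0.34, adjusted p = 0.00057), the template-independent DNA polymerase of lymphoid progenitors, and more Hlf (2.51 ± 0.23, adjusted p = 0.00045), a transcription factor of haematopoietic stem cells. Mecom (2.09 ± 0.48, adjusted p = 0.028) and the cytokine receptor gene Flt3 (1.90 ± 0.24, adjusted p = 0.0021) were also higher in LSK cells; a further Mecom row read 0.93. MP cells had more of the erythroid genes Car1 (-4.42 ± 0.49, adjusted p = 0.0014), Cldn13 (-3.86 ± 0.48, adjusted p = 0.0022) and Rhag (-3.62 ± 0.45, adjusted p = 0.0022), and more of the granulocytic genes Ms4a3 (-3.51 ± 0.36) and Elane (-3.37 ± 0.35; both adjusted p = 0.00084). The sizes for Mecom, Cldn13 and Rhag are lower bounds, since 1 group read below the array medians. Parp2 read -0.73 ± 0.26 (adjusted p = 0.12) and Parp1 0.02 ± 0.15 (adjusted p = 0.93).

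The marker lists moved with the cell type. Of 26 measured stem cell genes, 8 were higher in LSK cells, among them Hoxa5 (1.64 ± 0.28) and Meis1 (1.39 ± 0.28), while 0 were lower and 18 did not pass (12 higher adjusted over the list alone). For the stem cell list, camera gave adjusted p = 1.47e-07, and adjusted p = 0.018 with an estimated correlation. Of 22 granulocyte and monocyte progenitor genes, 12 were lower in LSK cells (1 higher and 15 lower adjusted over the list alone). For the granulocyte and monocyte list, camera gave adjusted p = 4.93e-12, and adjusted p = 0.0437 with an estimated correlation. Of 20 erythroid genes, 11 were lower (15 adjusted over the list alone). For the erythroid list, camera gave adjusted p = 4.49e-14, and adjusted p = 0.0575 with an estimated correlation. The lymphoid priming list was higher in LSK cells, with 3 of 14 members called (4 adjusted over the list alone; adjusted p = 0.0111, adjusted p = 0.104 with an estimated correlation).

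Several cell cycle and repair lists were lower in LSK than in MP cells, with most members uncalled. Of 37 DNA replication and S phase genes, 10 were lower and 0 higher (19 lower adjusted over the list alone), with Gins1 at -1.90 ± 0.29 and Ccne1 at -1.54 ± 0.27. For the replication list, camera gave adjusted p = 4.31e-12, and adjusted p = 0.000857 with an estimated correlation. The mitosis list had 3 of 34 members lower, including Bub1 (-1.06 ± 0.21; 16 adjusted over the list alone; adjusted p = 1.23e-10, adjusted p = 0.0437 with an estimated correlation). Double-strand break repair had 6 of 34 lower, including Polq (-1.57 ± 0.18; 10 adjusted over the list alone). For the double-strand break repair list, camera gave adjusted p = 3.47e-07, and adjusted p = 0.0371 with an estimated correlation. Nucleotide excision repair had 1 of 18 lower (1 adjusted over the list alone; adjusted p = 0.0013, adjusted p = 0.0371 with an estimated correlation), and the NRF2 list 1 of 20 (8 adjusted over the list alone; adjusted p = 0.0013, adjusted p = 0.0371 with an estimated correlation).

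Further lists called between LSK and MP cells had small medians or few called members. T and NK cell genes were higher in LSK cells (2 of 18 called, including Thy1 at 1.61 ± 0.39; 4 adjusted over the list alone; adjusted p = 0.00758, adjusted p = 0.0495 with an estimated correlation). Immediate early genes had 22 of 23 values above 0 (1 higher, and 1 adjusted over the list alone; adjusted p = 0.000843, adjusted p = 0.304 with an estimated correlation). Of 14 dendritic cell genes, 1 was higher (3 higher and 1 lower adjusted over the list alone; median 0.383; adjusted p = 0.0161, adjusted p = 0.0688 with an estimated correlation). B lymphocyte genes had a median of 0.380 with 0 of 17 called (2 higher adjusted over the list alone; adjusted p = 0.021, adjusted p = 0.0713 with an estimated correlation). Endothelial and stromal genes had 0.257, with 2 of 15 higher by either count (adjusted p = 0.00586, adjusted p = 0.104 with an estimated correlation). Heat shock genes had a median of -0.386, with 2 of 10 lower, including Hsph1 at -1.11 ± 0.16 (3 lower adjusted over the list alone; adjusted p = 0.00126, adjusted p = 0.145 with an estimated correlation), and ribosomal protein genes -0.140 with 0 of 29 called by either count (adjusted p = 0.00663, adjusted p = 0.318 with an estimated correlation). In all, 1200 of 22961 rows were called, 297 higher and 903 lower in LSK cells. A fit to the 4 arrays alone called 51 and a further quantile normalisation 726. Values varied less over the rows of the LSK arrays (SD 1.988 and 1.934) than of the MP arrays (2.126 and 2.054). The median difference over all rows was 0.094, and 0.032 after the further normalisation. How far these unequal distributions shaped the counts and the lists with small medians was not tested. Leaving out WT MP unirradiated pool 1 left 186 calls. Of 58 called named genes, 22 stayed called whichever array was left out.

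In WT LSK cells, irradiation raised Tnip3, an inhibitor of NF-kappaB signalling, 21.2-fold (9.97 ± 0.40 against 5.56 ± 0.48, SD, n = 2). The change was 4.41 ± 0.41 log2 units (adjusted p = 0.00024). Tnfsf4, which encodes OX40 ligand, rose by 4.25 ± 0.31 (adjusted p = 7.1e-05), Trp53inp1, a p53 target, by 3.40 ± 0.25 (adjusted p = 7.1e-05), and Polk, a translesion DNA polymerase, by 3.28 ± 0.24 (adjusted p = 7.1e-05). Among the 8 largest rises were also Ddias (3.29 ± 0.34), Cd55 (3.16 ± 0.41), the death receptor gene Tnfrsf10b (3.13 ± 0.26) and Gtse1 (3.05 ± 0.25). The orphan nuclear receptor gene Nr4a1 fell by 3.94 ± 0.49 (adjusted p = 0.0019), and further large falls were those of Tiparp (-2.32 ± 0.34, adjusted p = 0.005), Klf6 (-2.25 ± 0.37, adjusted p = 0.011), Aspm (-2.21 ± 0.41, adjusted p = 0.018), Ier3 (-2.15 ± 0.43, adjusted p = 0.028) and Rgs1 (-2.13 ± 0.37, adjusted p = 0.014). Zc3h3 (-3.39 ± 0.67, adjusted p = 0.027) and Igha (-2.17 ± 0.47, adjusted p = 0.04) fell on 1 row each, and their other rows read -0.31 and -0.32. Over the 4 radiation responses, 28 of 126 called named-gene results had 1 group below the array medians, so their sizes are lower bounds. In WT LSK cells these were Tnfsf4, Zc3h3, Fas, Cdc25c, Mx1 and Mx2.

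Part of the p53 targets rose in WT LSK cells. Of 32 arrest and feedback genes, 15 rose, 0 fell and 17 did not pass (19 rose adjusted over the list alone; median 1.010; camera adjusted p = 3.12e-19, adjusted p = 0.000551 with an estimated correlation), including Ercc5 (2.82 ± 0.29) and Phlda3 (2.76 ± 0.28). Of 18 apoptosis targets, 8 rose and 10 did not pass (11 rose and 2 fell adjusted over the list alone), including Fas (2.69 ± 0.36) and Pmaip1, which encodes Noxa (1.94 ± 0.21). For the apoptosis list, camera gave adjusted p = 2.25e-11, and adjusted p = 0.0402 with an estimated correlation. Interferon-stimulated genes had 7 of 31 members higher (13 adjusted over the list alone), among them Cxcl10 (2.64 ± 0.57), Mx2 (2.29 ± 0.27) and Mx1 (1.76 ± 0.16). For the interferon list, camera gave adjusted p = 2.25e-11, and adjusted p = 0.1 with an estimated correlation. Of 34 mitosis genes, 7 fell (17 adjusted over the list alone), including the mitotic kinase gene Plk1 (-2.11 ± 0.24) and Cdc25c (-1.54 ± 0.24). For the mitosis list, camera gave adjusted p = 1.69e-11, and adjusted p = 0.0738 with an estimated correlation. Of 23 immediate early genes, 5 fell (1 rose and 16 fell adjusted over the list alone). For the immediate early list, camera gave adjusted p = 1.32e-11, and adjusted p = 0.1 with an estimated correlation.

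Lineage lists moved less in WT LSK cells. Lymphoid priming genes had a median of -0.268 (adjusted p = 0.0375, adjusted p = 0.218 with an estimated correlation), dendritic cell genes -0.356 (adjusted p = 0.0449, adjusted p = 0.132 with an estimated correlation) and endothelial and stromal genes -0.225 (adjusted p = 0.0252, adjusted p = 0.219 with an estimated correlation). Each had 0 called members, over all genes and adjusted over the list alone. These list calls, and that of the mast cell list, were each lost in some fits with 1 array left out, the dendritic call most often. The mast cell list had a median of 0.320 (1 of 12 rose, Mcpt8 at 1.60 ± 0.35; 2 adjusted over the list alone; adjusted p = 0.0219, adjusted p = 0.1 with an estimated correlation). Outside the called lists, the ATF4 list members went both ways, with Sesn2 higher (1.94 ± 0.28) and Ppp1r15a (-1.23 ± 0.24) and Slc3a2 (-1.07 ± 0.16) lower. The poly(ADP-ribose) glycohydrolase gene Parg (0.77 ± 0.18), Parp14 (1.47 ± 0.25), Nfkbib (0.92 ± 0.18), Polq (0.79 ± 0.18), Igsf6 (1.28 ± 0.26) and Rpgrip1 (0.73 ± 0.16) rose, while Ccl4 (-1.30 ± 0.24) and Gp9 (-0.85 ± 0.19) fell. Parp2 (0.43 ± 0.26, adjusted p = 0.47) and Parp1 (-0.15 ± 0.15, adjusted p = 0.71) did not pass. In all, 413 rows passed, 270 higher and 143 lower, and 204 and 86 of these changed at least 2-fold. Leaving out 1 array gave 242 to 537. Of 40 called named genes, 20 stayed called whichever array was left out, while Polq, Parg, Rpgrip1, Mcpt8, Gp9 and Igha stayed in 2 to 8 of 16 such fits. With the 8 LSK arrays fitted alone, 35 passed, 28 higher and 7 lower, all of them among the 413; Tnip3, Tnfsf4, Trp53inp1, Polk, Ddias, Tnfrsf10b, Gtse1, Nr4a1, Rgs1, Ercc5, Phlda3, Pmaip1, Mx1, Mx2 and Plk1 stayed called. The 22 other genes given above as changed lost their call, with adjusted p from 0.061 (Tiparp) to 0.3 (Parg).

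**Figure D1:**
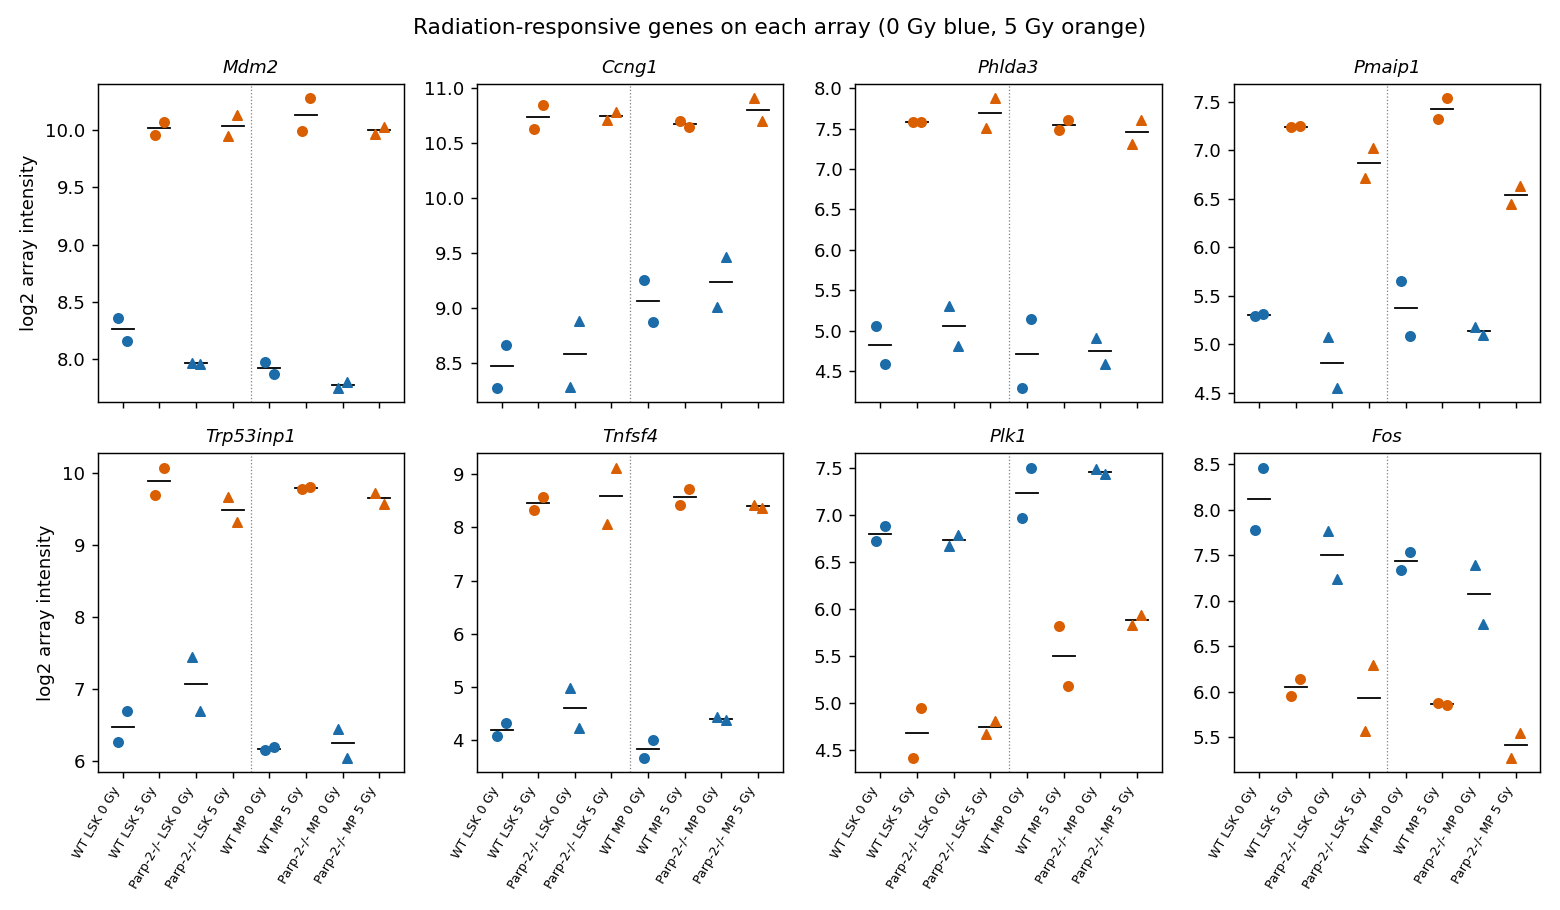
Log2 array intensity (vertical axis) of 8 radiation-responsive genes in the 8 groups (horizontal axis); each point is 1 pool, circles are WT and triangles Parp-2-/- cells, blue is 0 Gy and orange 5 Gy, and each line is the mean of the 2 pools. Mdm2, Ccng1, Phlda3, Pmaip1, Trp53inp1 and Tnfsf4 rose and Plk1 and Fos fell in all 4 responses.

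In Parp-2-/- LSK cells, Tnip3 rose by 4.82 ± 0.41 (adjusted p = 0.00016), the thiamine transporter gene Slc19a2 by 4.40 ± 0.23 (adjusted p = 3.6e-06), Ddias by 4.07 ± 0.34 (adjusted p = 0.00016) and Tnfsf4 by 3.97 ± 0.31 (adjusted p = 9.7e-05). Next came Cxcl10 (3.47 ± 0.57, adjusted p = 0.0098), the NADPH oxidase gene Cybb (3.40 ± 0.48, adjusted p = 0.0034), Eda2r (3.31 ± 0.47, adjusted p = 0.0034) and Cd55 (3.30 ± 0.41, adjusted p = 0.0019). The largest falls were those of Isca1 (-3.43 ± 0.54), Fosb (-3.38 ± 0.53), Nr4a1 (-2.72 ± 0.49), Nr4a2 (-2.69 ± 0.58), Klf6 (-2.69 ± 0.37), Rgs2 (-2.63 ± 0.29), Prc1 (-2.63 ± 0.35) and Kpna2 (-2.60 ± 0.37), with adjusted p from 0.00074 to 0.043. The sizes for Slc19a2, Eda2r, Isca1, Fas, Plk1, Mx1 and Mx2 are lower bounds. Parp2 (0.39 ± 0.26, adjusted p = 0.64) and Parp1 (-0.45 ± 0.15, adjusted p = 0.22) did not pass.

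Mitosis genes formed the largest called group that fell in Parp-2-/- LSK cells. Of 34 measured, 15 fell, 0 rose and 19 did not pass (28 fell adjusted over the list alone; median -0.996), including Kif23 (-2.15 ± 0.19), Plk1 (-1.99 ± 0.24) and the spindle gene Tpx2 (-1.92 ± 0.28). For the mitosis list, camera gave adjusted p = 2.45e-33, and adjusted p = 0.00379 with an estimated correlation. Of 32 p53 arrest and feedback genes, 13 rose (17 rose and 1 fell adjusted over the list alone), including Phlda3 (2.63 ± 0.28) and Polk (2.21 ± 0.24). For the arrest list, camera gave adjusted p = 5.82e-20, and adjusted p = 0.000508 with an estimated correlation. Of 18 apoptosis targets, 9 rose (10 adjusted over the list alone), including Fas (3.28 ± 0.36), Tnfrsf10b (2.65 ± 0.26) and Pmaip1 (2.07 ± 0.21). For the apoptosis list, camera gave adjusted p = 9.61e-12, and adjusted p = 0.0229 with an estimated correlation. Immediate early genes had 1 rise and 7 falls among 23 (1 rise and 13 falls adjusted over the list alone). For the immediate early list, camera gave adjusted p = 1.04e-11, and adjusted p = 0.156 with an estimated correlation. Interferon-stimulated genes had 3 of 31 higher, including Mx2 (2.27 ± 0.27) and Mx1 (1.67 ± 0.16; 9 adjusted over the list alone). For the interferon list, camera gave adjusted p = 0.00297, and adjusted p = 0.502 with an estimated correlation. The lymphoid priming list had a median of -0.367 (0 called, 2 lower adjusted over the list alone; adjusted p = 0.0324, adjusted p = 0.286 with an estimated correlation).

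Single members of other lists also changed: Icam1 rose by 1.11 ± 0.18 (adjusted p = 0.0087), Parg by 0.98 ± 0.18 (adjusted p = 0.018) and Elane by 1.63 ± 0.35 (adjusted p = 0.041), and the anti-apoptotic gene Mcl1 fell by 1.09 ± 0.22 (adjusted p = 0.029). Of the ATF4 list, Vldlr fell (-1.66 ± 0.25) and Sesn2 (1.36 ± 0.28) and Ddit4 (0.78 ± 0.14) rose. In all, 337 rows passed, 167 higher and 170 lower, and leaving out 1 array gave 189 to 469. Of 35 called named genes, 25 stayed called whichever array was left out, while Nr4a2, Elane and Sesn2 stayed in 5 to 7 of 16 such fits. The 8 LSK arrays fitted alone gave 51, 35 higher and 16 lower, all among the 337. There Tnip3, Slc19a2, Ddias, Tnfsf4, Fosb, Klf6, Rgs2, Kif23, Plk1, Phlda3, Polk, Fas, Tnfrsf10b, Pmaip1, Mx1 and Mx2 stayed called. The 17 other genes given above as changed lost their call, with adjusted p from 0.05 (Eda2r) to 0.27 (Elane). The 4 arrays of the groups alone called 0 rows in limma (1718 at an unadjusted p under 0.05, smallest adjusted p = 0.0885).

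In WT MP cells, Tnfsf4 rose by 4.73 ± 0.31 (adjusted p = 2e-05), Tnip3 by 4.33 ± 0.41 (adjusted p = 0.00029), Fas by 4.04 ± 0.36 (adjusted p = 0.0002) and Prrg4 by 3.79 ± 0.43 (adjusted p = 0.00095). Tnfrsf10b (3.72 ± 0.26), Trp53inp1 (3.61 ± 0.25), the co-stimulatory ligand gene Cd80 (3.54 ± 0.26, with 1.74 on its other row) and Plk2 (3.48 ± 0.54) followed. The largest falls were those of Tlcd4 (-3.10 ± 0.51), Fosb (-2.65 ± 0.53), Klf6 (-2.36 ± 0.37), Nxpe2 (-2.07 ± 0.42), Aqp9 (4-fold lower), Plk1 (-1.73 ± 0.24), Fos (-1.57 ± 0.30) and Cenpf (-1.50 ± 0.20), with adjusted p from 0.003 to 0.047. The sizes for Tnfsf4, Tnip3, Fas, Tnfrsf10b, Cd80, Tlcd4, Eda2r, Mx1 and Mx2 are lower bounds here. Parp2 read 0.19 ± 0.26 and Parp1 0.15 ± 0.15 (both adjusted p = 1).

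Of 32 p53 arrest and feedback genes in WT MP cells, 15 rose, 0 fell and 17 did not pass (21 rose adjusted over the list alone; median 1.466), including Eda2r (3.03 ± 0.47), Phlda3 (2.83 ± 0.28) and Polk (2.67 ± 0.24). For the arrest list, camera gave adjusted p = 1.32e-42, and adjusted p = 2.67e-05 with an estimated correlation. Of 18 apoptosis targets, 8 rose (13 adjusted over the list alone). For the apoptosis list, camera gave adjusted p = 2.82e-27, and adjusted p = 0.00201 with an estimated correlation. Interferon-stimulated genes had 3 of 31 higher (12 adjusted over the list alone): Mx1 (2.67 ± 0.16), Mx2 (2.08 ± 0.27) and Rtp4 (2.05 ± 0.41). For the interferon list, camera gave adjusted p = 7.31e-19, and adjusted p = 0.0291 with an estimated correlation. Of 34 mitosis genes, 3 fell (21 adjusted over the list alone). For the mitosis list, camera gave adjusted p = 6.48e-25, and adjusted p = 0.00711 with an estimated correlation. Immediate early genes had 4 of 23 lower (7 adjusted over the list alone). For the immediate early list, camera gave adjusted p = 1.23e-10, and adjusted p = 0.118 with an estimated correlation.

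Erythroid markers were lower after irradiation in WT MP cells: 2 of 20 fell over all genes, 16 adjusted over the list alone, and all 20 values were below 0 (median -0.943; adjusted p = 1.59e-21, adjusted p = 0.0386 with an estimated correlation). The granulocyte and monocyte list moved the other way, with 20 of 22 values above 0 and 0 called (1 higher adjusted over the list alone; median 0.279; adjusted p = 3.16e-05, adjusted p = 0.218 with an estimated correlation). The mean erythroid level, relative to all arrays, was 0.59 and 1.31 in the unirradiated WT MP pools and -0.05 and -0.01 in the irradiated ones. The megakaryocyte list had a median of -0.219 (2 of 16 lower adjusted over the list alone; adjusted p = 0.0299, adjusted p = 0.265 with an estimated correlation), the lymphoid priming list -0.246 (adjusted p = 0.0376, adjusted p = 0.213 with an estimated correlation) and the T and NK cell list -0.146 (adjusted p = 0.0376, adjusted p = 0.118 with an estimated correlation), each with 0 members called over all genes, and the latter pair with 0 adjusted over the list alone. Those 3 list calls were lost when the 8 MP arrays were fitted alone (adjusted p = 0.0608, 0.0733 and 0.0573). Icam1 (1.15 ± 0.18) and Sesn2 (1.76 ± 0.28) rose outside the called lists. In all, 154 rows passed, 131 higher and 23 lower; the 8 MP arrays alone gave 390, 307 higher and 83 lower, 152 of them shared. Leaving out irradiated pool 1, irradiated pool 2 or unirradiated pool 2 left 47, 43 and 39 calls. Of 25 called named genes, 11 stayed called whichever array was left out, while Fosb, Nxpe2 and Rtp4 stayed in 4, 5 and 7 of 16 such fits.

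In Parp-2-/- MP cells, Tnfsf4 rose by 3.99 ± 0.31 (adjusted p = 7.4e-05), Fas by 3.94 ± 0.36 (adjusted p = 0.00033), Prrg4 by 3.92 ± 0.43 (adjusted p = 0.00084) and Cd80 by 3.46 ± 0.26 (adjusted p = 5.8e-05). Tnip3 (3.43 ± 0.41), Plk2 (3.40 ± 0.54), Trp53inp1 (3.39 ± 0.25) and Mybl1 (3.28 ± 0.33) completed the 8 largest rises. The largest falls were those of Fosb (-3.49 ± 0.53), Klf6 (-2.92 ± 0.37), the phosphatase gene Dusp1 (-2.05 ± 0.25), Rgs2 (-2.03 ± 0.29), Fos (-1.66 ± 0.30), Plk1 (-1.58 ± 0.24), Ccne1 (-1.52 ± 0.27) and the erythroid gene Hemgn (-1.41 ± 0.28), with adjusted p from 0.0018 to 0.047. Parp2 read -0.17 ± 0.26 and Parp1 0.01 ± 0.15 (both adjusted p = 1). The sizes for Tnfsf4, Fas, Cd80, Mx1 and Mx2 are lower bounds here too.

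Of 32 p53 arrest and feedback genes in Parp-2-/- MP cells, 16 rose and 16 did not pass (18 rose adjusted over the list alone; median 1.247), including Polk (2.96 ± 0.24) and Phlda3 (2.72 ± 0.28). For the arrest list, camera gave adjusted p = 2.63e-40, and adjusted p = 3.31e-05 with an estimated correlation. Of 18 apoptosis targets, 9 rose (10 adjusted over the list alone), including Tnfrsf10b (2.60 ± 0.26) and the apoptosome gene Apaf1 (1.68 ± 0.17). For the apoptosis list, camera gave adjusted p = 3.83e-21, and adjusted p = 0.00502 with an estimated correlation. Of 34 mitosis genes, 4 fell (12 adjusted over the list alone), including Cenpf (-1.32 ± 0.20). For the mitosis list, camera gave adjusted p = 3.33e-24, and adjusted p = 0.00763 with an estimated correlation. Of 23 immediate early genes, 5 fell (12 adjusted over the list alone). For the immediate early list, camera gave adjusted p = 3.92e-21, and adjusted p = 0.0335 with an estimated correlation. Mx1 (2.21 ± 0.16) and Mx2 (2.18 ± 0.27) were the 2 of 31 interferon-stimulated genes that rose (4 adjusted over the list alone). For the interferon list, camera gave adjusted p = 3.85e-10, and adjusted p = 0.124 with an estimated correlation.

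Of 20 erythroid genes in Parp-2-/- MP cells, 1 fell (7 adjusted over the list alone; median -0.659), with mean levels of 1.15 and 1.44 in the unirradiated and 0.45 and 0.84 in the irradiated pools. For the erythroid list, camera gave adjusted p = 5.69e-12, and adjusted p = 0.14 with an estimated correlation. The ATF4 list had 2 of 20 higher, Sesn2 (1.52 ± 0.28) and Ddit4 (0.96 ± 0.14), over a median of -0.275 (2 rises and 3 falls adjusted over the list alone; adjusted p = 0.0248, adjusted p = 0.239 with an estimated correlation). Heat shock genes had a median of -0.135 (0 of 10 called, 3 lower adjusted over the list alone; adjusted p = 0.00224, adjusted p = 0.269 with an estimated correlation) and megakaryocyte genes -0.191 (0 called by either count; adjusted p = 0.0289, adjusted p = 0.345 with an estimated correlation; adjusted p = 0.0597 with the 8 MP arrays alone). In all, 135 rows passed, 116 higher and 19 lower; the 8 MP arrays alone gave 365, 265 higher and 100 lower, 134 of them shared. Leaving out irradiated pool 1 or 2 left 56 and 43 calls, and leaving out unirradiated pool 1 or 2 left 48 and 45. Of 26 called named genes, 15 stayed called whichever array was left out, while Hemgn stayed in 4 of 16 such fits.

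The radiation responses of both genotypes were compared within each cell type. In MP cells, 94 rows rose and 10 fell in both genotypes, against 0.66 and 0.02 by chance, with 0 called in opposite directions and a correlation of log2 changes of 0.68 over all rows and 0.95 over the 185 rows called in either genotype. In LSK cells, 93 rose and 32 fell in both, against 1.96 and 1.06 by chance, with 1 opposite call; the correlation was 0.33 over all rows and 0.72 over 624 called rows, and the first of these was 0.22 without Parp-2-/- LSK irradiated pool 2. The called rows were picked by their changes in these same comparisons, which raises the correlation over them. Spread between pools was 0.314 to 0.351 in LSK and 0.162 to 0.225 in MP cells, and a larger spread lowers a correlation. These correlations therefore do not compare the effect of genotype between cell types. Between LSK and MP cells, 89 rises and 6 falls were shared in WT (correlation 0.45) and 66 and 11 in Parp-2-/- (0.39). No array served in both comparisons of a pair, and genes are not independent replicates, so no p-value is given.

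A set of 57 rows rose and 5 fell in all 4 responses. With each cell type fitted alone the numbers were 17 and 1, and Mdm2, Ccng1, Phlda3, Pmaip1, Trp53inp1, Tnfrsf10b, Tnfsf4, Tnip3, Polk, Ddias, Mx1, Mx2 and Slc19a2 were among the 17. Mdm2, the ubiquitin ligase that limits p53, rose by 1.76, 2.07, 2.21 and 2.22 ± 0.15 (WT LSK, Parp-2-/- LSK, WT MP, Parp-2-/- MP), and Ccng1, the p53 target cyclin G1, by 2.28, 2.16, 1.62 and 1.57 ± 0.23. Mybl1 rose by 2.91, 3.25, 3.31 and 3.28 ± 0.33. The 5 that fell were Plk1, Cenpf, Fos, Dusp1 and Klf6. Mdm2, Ccng1 and any other gene that the naming rule did not take in a given response were chosen here after their values were seen.

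**Figure D2:**
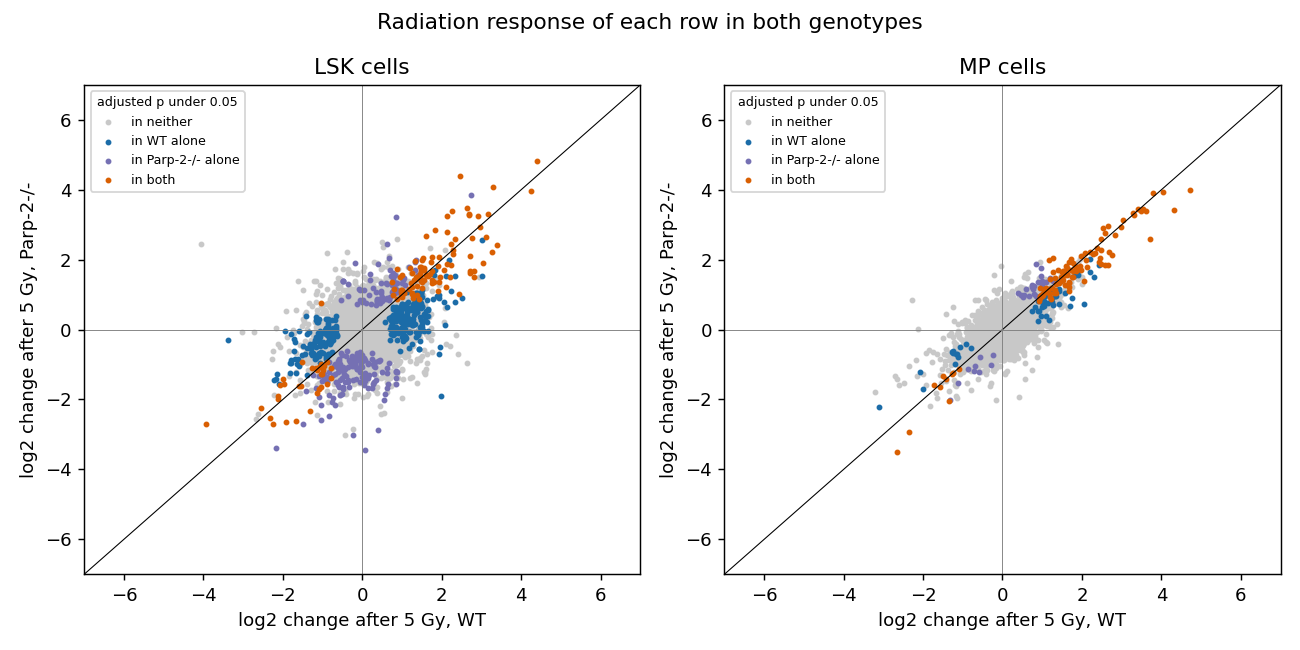
Log2 change after 5 Gy in WT (horizontal axis) against Parp-2-/- cells (vertical axis), for LSK cells on the left and MP cells on the right; each point is 1 of 22961 rows, coloured by whether it passed in neither genotype, in 1 of them or in both, and the diagonal marks equal changes. The correlation over all rows is 0.33 in LSK and 0.68 in MP cells. LSK pools vary more, so these values do not compare the effect of genotype between cell types.

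The cell type by irradiation interaction in WT asks whether LSK and MP cells responded differently. Of 22961 rows, 0 passed in limma (1272 at an unadjusted p under 0.05, 1148 by chance; smallest adjusted p = 0.419), and the fits with a block, with a weight for each cell type, to all rows and after a further quantile normalisation also called 0. Leaving out WT LSK unirradiated pool 1 or 2 gave 9 and 2 calls. Parp2 read 0.24 ± 0.36 (adjusted p = 0.99) and Parp1 -0.30 ± 0.22 (adjusted p = 0.97). Erythroid genes had 20 of 20 values above 0, with 0 called and 1 higher adjusted over the list alone (median 0.707; adjusted p = 5.31e-10, adjusted p = 0.743 with an estimated correlation). The endothelial and stromal list had a median of -0.194 with 0 of 15 called by either count (adjusted p = 0.042, adjusted p = 0.74 with an estimated correlation).

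The genotype by irradiation interaction asks whether loss of Parp-2 altered the response. In LSK cells, 2 rows passed, both higher: Olfr652, an olfactory receptor gene chosen after its values were seen (1.87 ± 0.23, adjusted p = 0.0467), and a row with several symbols (1.79 ± 0.23, adjusted p = 0.0467). At an unadjusted p under 0.05 there were 2187 rows, and 1066 with the 8 LSK arrays fitted alone, against 1148 by chance. That fit to the 8 LSK arrays called 0. Slc19a2, chosen after its values were seen, with rises of 2.46 ± 0.23 in WT and 4.40 ± 0.23 in Parp-2-/- LSK cells, had an interaction of 1.94 ± 0.33 (adjusted p = 0.085). Its unirradiated Parp-2-/- level lay below the array medians, so the size of this interaction is not measured. Parp2 read -0.04 ± 0.36 (adjusted p = 0.98) and Parp1 -0.30 ± 0.22 (adjusted p = 0.71). The mitosis list had a median of -0.473 (0 of 34 called, 3 lower adjusted over the list alone; adjusted p = 3.3e-05, adjusted p = 0.49 with an estimated correlation), interferon-stimulated genes -0.374 (0 of 31 called, 1 higher and 2 lower adjusted over the list alone; adjusted p = 0.0168, adjusted p = 0.58 with an estimated correlation) and mast cell genes -0.318 (0 of 12 by either count; adjusted p = 0.0497, adjusted p = 0.49 with an estimated correlation).

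In MP cells, 0 rows passed the interaction test in limma (199 at an unadjusted p under 0.05, fewer than the 1148 by chance), and every other fit called 0. Parp2 read -0.36 ± 0.36 and Parp1 -0.13 ± 0.22 (both adjusted p = 1), and Pmaip1, chosen after its values were seen, which rose by 2.07 in WT and 1.40 in Parp-2-/- MP cells, had an interaction of -0.66 ± 0.30 (adjusted p = 1). The 7 lists called here had small medians and 0 called members, over all genes and adjusted over the list alone. Immediate early genes had a median of -0.289 and interferon-stimulated genes -0.127 (both adjusted p = 0.0024, adjusted p = 0.5 with an estimated correlation), p53 apoptosis targets -0.182 (adjusted p = 0.00846, adjusted p = 0.5 with an estimated correlation) and NRF2 targets -0.159 (adjusted p = 0.0119, adjusted p = 0.21 with an estimated correlation). DNA replication genes had -0.130 (adjusted p = 0.0302, adjusted p = 0.21 with an estimated correlation), granulocyte and monocyte genes -0.137 (adjusted p = 0.00904, adjusted p = 0.5 with an estimated correlation) and erythroid genes 0.278 (adjusted p = 0.00276, adjusted p = 0.52 with an estimated correlation). Without WT MP unirradiated pool 2, the granulocyte and monocyte list and the erythroid list turned direction (adjusted p = 0.984 and 0.816), and 1 of the 7 list calls was left. Without Parp-2-/- MP unirradiated pool 1, 0 were left, and fry called 0.

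**Figure D3:**
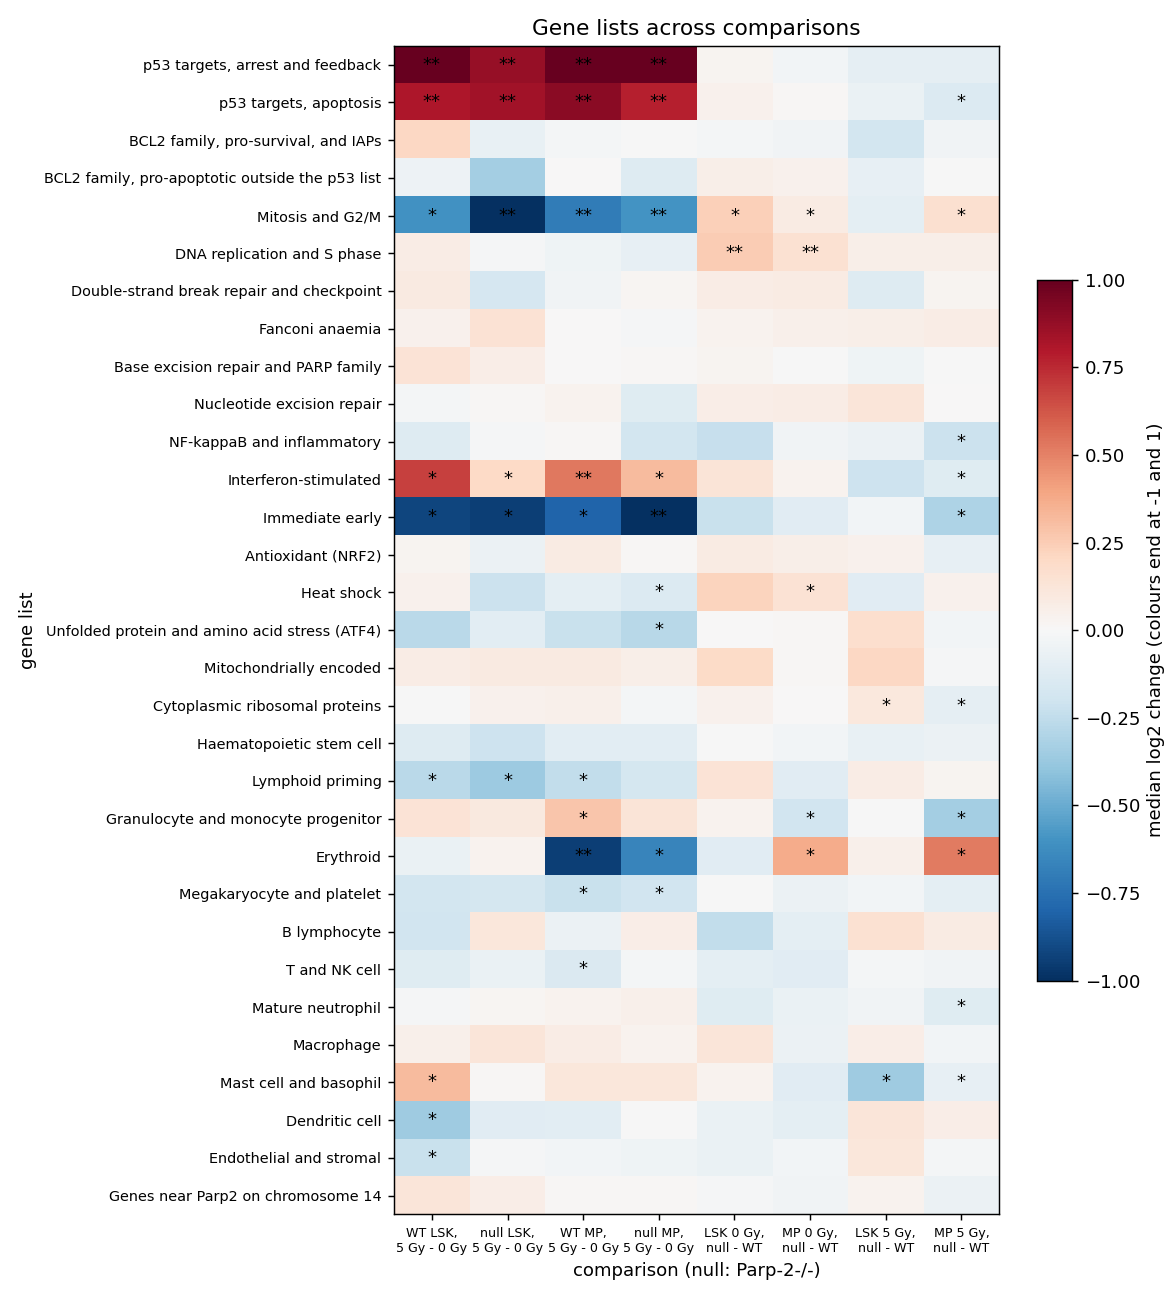
Median log2 change of the measured members of each gene list (rows) in the 4 radiation responses and the 4 genotype differences (columns; null is Parp-2-/-), red for higher and blue for lower, with colours ending at -1 and 1. An asterisk marks an adjusted p under 0.05 by camera, and a pair of asterisks the same also with an estimated correlation, as for the p53 targets in all 4 responses.

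Before irradiation, 0 rows differed between Parp-2-/- and WT LSK cells in limma (smallest adjusted p = 0.0515, shared by 9 rows). An unadjusted p under 0.05 was reached by 2137 rows, against 1148 by chance. With the 8 LSK arrays fitted alone it was reached by 1069, so the excess is not evidence of a genotype effect. The block fit called 2, the fit to all rows 5, a further quantile normalisation 14, and the 8 LSK arrays alone 0; leaving out WT LSK unirradiated pool 1 gave 148. Slc19a2, chosen after its values were seen, had a value of -1.71 ± 0.23 (adjusted p = 0.0515), a bound on the size because its Parp-2-/- level of 3.56 lay below the array medians. DNA replication genes had 29 of 37 values above 0 in Parp-2-/- LSK cells, with 0 called and 2 higher and 1 lower adjusted over the list alone (median 0.251; camera adjusted p = 4.54e-05, adjusted p = 0.0184 with an estimated correlation). The mitosis list had 28 of 34 above 0 and 0 called by either count (median 0.241; adjusted p = 4.54e-05, adjusted p = 0.466 with an estimated correlation).

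In unirradiated MP cells, Ccnb1ip1 was higher in Parp-2-/- cells (7.11 ± 0.39 against 3.30 ± 0.00, SD, n = 2; 3.81 ± 0.19, adjusted p = 2.4e-06). The WT level lay below the array medians and is not shown to be above background, so the size of the difference is a lower bound. It encodes a RING finger protein known for its part in meiotic crossing over, and it is the protein-coding gene next to Parp2 on chromosome 14. It was the only row of 22961 called there, and the 8 MP arrays alone called it as well (adjusted p = 0.0001). An unadjusted p under 0.05 was reached by 247 rows, and by 832 with the 8 MP arrays alone, against 1148 by chance. DNA replication genes had 35 of 37 values above 0, with 0 called by either count (median 0.152; adjusted p = 4.82e-07, adjusted p = 0.00611 with an estimated correlation), and mitosis genes 26 of 34, also with 0 called (median 0.079; adjusted p = 0.00486, adjusted p = 0.375 with an estimated correlation). Mean levels of the replication list are given over both irradiation states. They were 0.24 to 0.37 in Parp-2-/- and 0.19 to 0.20 in WT MP arrays. In LSK arrays they were -0.22 to -0.12 against -0.42 to -0.27. The mean genotype difference over both cell types was 0.21 log2 units on the 8 unirradiated and 0.10 on the 8 irradiated arrays.

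Camera called 2 lineage lists between the unirradiated MP groups, which the other list tests did not. Erythroid genes had 17 of 20 values above 0 in Parp-2-/- cells (median 0.374; adjusted p = 3.04e-08, adjusted p = 0.345 with an estimated correlation), and granulocyte and monocyte genes 1 of 22 (median -0.195; adjusted p = 0.000479, adjusted p = 0.375 with an estimated correlation), with 0 members of either called by either count. Fry gave adjusted p = 0.63 for each. Both calls were lost without WT MP unirradiated pool 1 (adjusted p = 0.977 for the erythroid list and 0.926 for the other, which turned direction). Heat shock genes had a median of 0.145 (1 higher and 1 lower of 10 adjusted over the list alone; adjusted p = 0.0386, adjusted p = 0.375 with an estimated correlation; adjusted p = 0.0666 with the 8 MP arrays alone).

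After irradiation, 4 rows differed between Parp-2-/- and WT LSK cells, 3 higher and 1 lower. The 8 LSK arrays alone called 0, as did the weighted fit. An unadjusted p under 0.05 was reached by 2193 rows, and by 1080 with the 8 LSK arrays alone, against 1148 by chance. Dmac2, which encodes a mitochondrial protein, was higher by 1.53 ± 0.18 (6.98 ± 0.10 against 5.46 ± 0.29, SD, n = 2; adjusted p = 0.016, adjusted p = 0.43 with the 8 LSK arrays alone). Olfr652, chosen after its values were seen, read 1.47 ± 0.16 (adjusted p = 0.0164), and the other calls carried several symbols. Mast cell genes had 1 of 12 values above 0 (1 lower adjusted over the list alone; median -0.358; adjusted p = 0.00491, adjusted p = 0.146 with an estimated correlation) and ribosomal protein genes 27 of 29 (0 called by either count; median 0.105; adjusted p = 0.0219, adjusted p = 0.742 with an estimated correlation).

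In irradiated MP cells, Ccnb1ip1 was again higher in Parp-2-/- cells (6.92 ± 0.01 against 3.39 ± 0.12, SD, n = 2; 3.52 ± 0.19, again a lower bound, adjusted p = 6.2e-06), and Myh10, a non-muscle myosin heavy chain gene, was higher by 1.38 ± 0.18 (adjusted p = 0.043, adjusted p = 0.11 with the 8 MP arrays alone, and called in 2 of 16 fits with 1 array left out). These were the 2 called rows (411 at an unadjusted p under 0.05, and 1179 with the 8 MP arrays alone). In LSK cells Ccnb1ip1, chosen there after its values were seen and below the array medians on all 8 arrays, read 0.32 ± 0.19 before (adjusted p = 0.65) and 0.83 ± 0.19 after irradiation (adjusted p = 0.22). The pro-apoptotic gene Pmaip1, also chosen afterwards, had a value of -0.89 ± 0.21 in irradiated MP cells (adjusted p = 1).

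The 10 lists called by camera in irradiated MP cells had 0 members called over all genes, and 0 adjusted over the list alone except where given. Fry called 0 of these lists (adjusted p from 0.425 to 0.655). The calls of the p53 apoptosis, interferon, ribosomal protein, neutrophil and mast cell lists were each lost in some fits with 1 array left out. Erythroid genes had 20 of 20 values above 0 in Parp-2-/- cells (4 higher adjusted over the list alone; median 0.519; adjusted p = 2.84e-20, adjusted p = 0.121 with an estimated correlation), and granulocyte and monocyte genes 0 of 22 (median -0.336; adjusted p = 5.57e-13, adjusted p = 0.121 with an estimated correlation). Immediate early genes had a median of -0.310 (adjusted p = 1.33e-07, adjusted p = 0.213 with an estimated correlation), NF-kappaB genes -0.213 (adjusted p = 0.000348, adjusted p = 0.213 with an estimated correlation), p53 apoptosis targets -0.137 (1 of 18 lower adjusted over the list alone) and mitosis genes 0.163 (adjusted p = 0.000101, adjusted p = 0.213 with an estimated correlation). For the apoptosis list, camera gave adjusted p = 0.00066, and adjusted p = 0.213 with an estimated correlation. Interferon-stimulated genes (median -0.120; adjusted p = 0.0135, adjusted p = 0.475 with an estimated correlation), ribosomal protein genes (-0.086; adjusted p = 0.00574, adjusted p = 0.381 with an estimated correlation), neutrophil genes (-0.119; 1 of 16 lower adjusted over the list alone; adjusted p = 0.0214, adjusted p = 0.261 with an estimated correlation) and mast cell genes (-0.082; 1 of 12 lower adjusted over the list alone; adjusted p = 0.0202, adjusted p = 0.213 with an estimated correlation) had smaller values. The neutrophil call was lost with the 8 MP arrays alone (adjusted p = 0.0914).

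**Figure D4:**
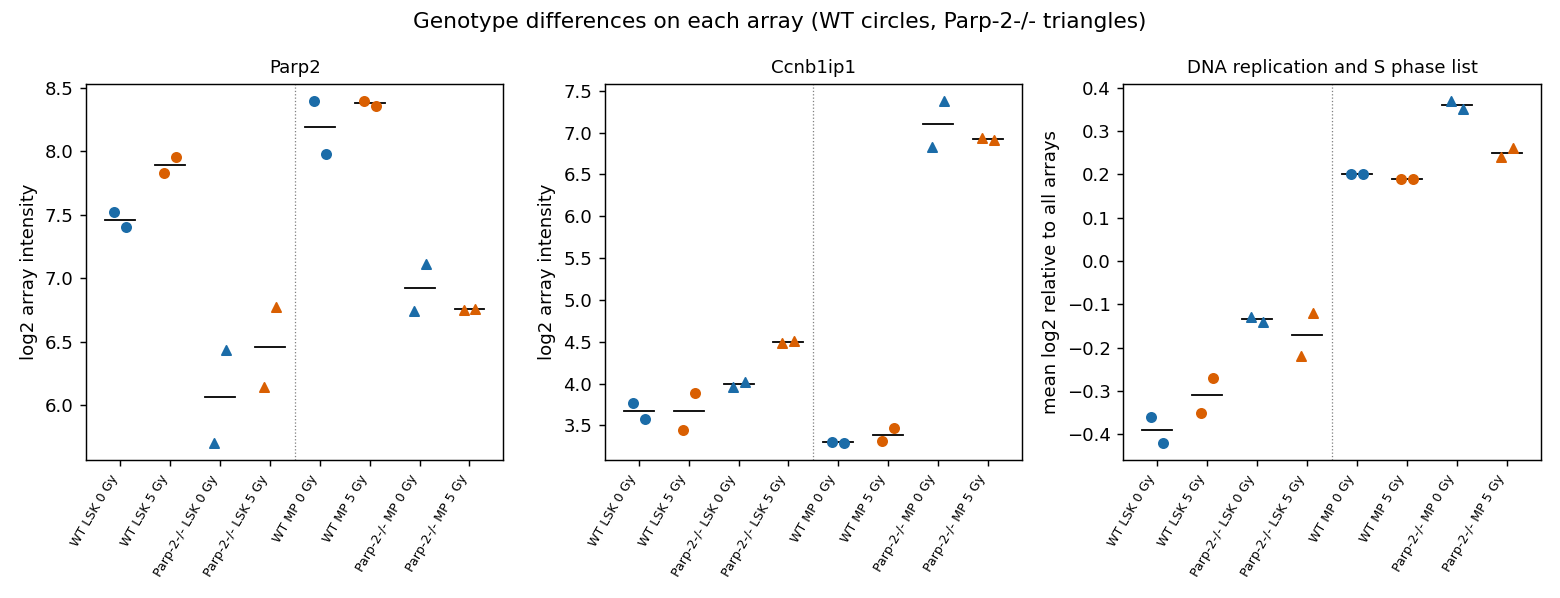
Parp2 and Ccnb1ip1 as log2 array intensity and the mean level of the DNA replication and S phase list relative to all arrays (vertical axes) in the 8 groups (horizontal axis); each point is 1 pool, circles are WT and triangles Parp-2-/- cells, blue is 0 Gy and orange 5 Gy, and lines are means of 2 pools. Ccnb1ip1 lies at 6.83 to 7.38 on Parp-2-/- MP arrays and at 3.29 to 3.47 on WT MP arrays.

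Of the 31 lists, 7 were called in none of the 12 comparisons. Base excision repair and the PARP family (31 measured) came closest in irradiated WT MP cells (adjusted p = 0.0532), and 3 of its members rose in irradiated WT LSK cells (5 higher and 1 lower adjusted over the list alone). The Fanconi anaemia list (14) had its smallest adjusted p = 0.0582 in LSK against MP cells, with Fancd2 lower in LSK cells (-1.36 ± 0.23). The smallest adjusted p = 0.36 of the pro-survival BCL2 and IAP list (12) and adjusted p = 0.21 of the other pro-apoptotic BCL2 genes (12) left both uncalled, with 1 called member each over the 12 comparisons (the same count adjusted over the list alone). Macrophage genes (16; adjusted p = 0.252), mitochondrially encoded genes (2; adjusted p = 0.359) and the genes near Parp2 (27; adjusted p = 0.503) had no list call either; in unirradiated and in irradiated MP cells the called member of the latter was Ccnb1ip1 (1 higher and 1 lower adjusted over the list alone).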

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

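The tests of explanations in this part, the splits of the MP and LSK arrays, the genotype average and its comparison between cell types were chosen after the result was seen.

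Ccnb1ip1 was higher in Parp-2-/- than in WT MP cells by at least 3.67 log2 units over both irradiation states, since the WT arrays read below the array medians; the comparison of genotype effects between cell types gave 3.09 ± 0.19 (adjusted p = 3e-05, the only call among 22961 rows), but all 8 LSK arrays also read below the medians, so its size is not measured. A different share of erythroid cells in the sorts is argued against, since both WT MP arrays whose erythroid level lay inside the Parp-2-/- range stayed at least 3.53 log2 units below the lowest Parp-2-/- array. Both (0.59 and 1.31) are unirradiated, while the range of 0.45 to 1.44 spans both irradiation states. Among unirradiated arrays the range is 1.15 to 1.44, which holds the WT array at 1.31. The irradiated WT arrays (-0.05 and -0.01) lay below the range, so no match exists there. Sequence carried along with the targeted locus, a technical explanation by strain origin, might account for it. Of 26 listed genes near Parp2, 5 passed an unadjusted p of 0.05 in MP cells, against 1.49 expected from the 5.7% of all rows (exact binomial p = 0.015). That test takes neighbouring genes on the same arrays as independent, so its p-value cannot decide this. Among these 5, Pnp read -0.68 and -0.62 in unirradiated and irradiated MP cells but 0.28 and 0.22 in LSK cells. Osgep read -0.44 and -0.42 in MP and -0.55 and -0.40 in LSK cells. An effect of lost Parp-2 on its neighbour, at the same 3.67 log2 units, cannot be told apart from carried sequence, because every Parp-2-/- array carries both the lost gene and the segment around it.

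More rows were called after irradiation in LSK than in MP cells (413 against 154 in WT), although the interaction of cell type and irradiation called 0. Unequal spread shared in 1 fit likely accounts for the order of the counts: with each cell type fitted alone, WT LSK had 35 calls and WT MP 390, and the spread between pools was 0.314 to 0.351 in LSK and 0.162 to 0.225 in MP cells. A larger response in LSK cells stays open. Over the 95 rows called in both, the median ratio of the LSK to the MP change was 0.97, with quartiles of 0.80 and 1.23 on either side of 1.

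The DNA replication list was higher in Parp-2-/- cells of both types before irradiation. Myeloid progenitors carried into the Parp-2-/- LSK sort are argued against, since the 42 erythroid, granulocyte and monocyte genes had a median of -0.047 (quartiles -0.207 and 0.185), where the replication change would need 0.48. A different mix of lineages in the MP sort was not tested. There the erythroid list had a median of 0.374 and the granulocyte and monocyte list -0.195. A shift shared by unrelated lists was not settled. The 29 ribosomal protein genes had medians of 0.043 in LSK (quartiles 0.002 and 0.090) and 0.001 in MP cells (-0.038 and 0.014), against 0.251 and 0.152 for replication. They are a single list at mean levels of 11.15 and 11.26, far above the array medians, where a small shift may not show. In MP cells the heat shock list had a median of 0.145, near that of replication. More cycling cells in Parp-2-/- marrow remains a possible biological explanation, which these arrays cannot decide: the mitosis list had medians of 0.241 in LSK and 0.079 in MP cells, with adjusted p = 0.466 and adjusted p = 0.375 with an estimated correlation.

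With both irradiation states averaged and each cell type fitted alone, 4 rows differed between genotypes in MP cells, 1 higher and 3 lower; among the 18 balanced splits of the 8 MP arrays, 1, the real one, reached this and the highest other called 1. In LSK cells 0 rows were called in limma (1046 at an unadjusted p under 0.05), a count that all 18 of 18 splits reach whatever the data, so the splits test nothing there; the highest other also called 0. So few splits allow no share under 0.05.

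Tests of a difference between groups flagged the remaining results. In the LSK genotype by irradiation interaction, Olfr652, chosen after its values were seen, had 1.87 ± 0.23 and a row with several symbols 1.79 ± 0.23 (both adjusted p = 0.047). The same interaction gave list medians of -0.473 for mitosis (adjusted p = 0.49 with an estimated correlation), -0.374 for interferon-stimulated genes (0.58) and -0.318 for mast cell genes (0.49).

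The MP genotype by irradiation interaction gave list medians of -0.182 for p53 apoptosis targets, -0.127 for interferon-stimulated, -0.289 for immediate early and -0.137 for granulocyte and monocyte genes (each adjusted p = 0.5 with an estimated correlation). DNA replication genes had -0.130 and NRF2 targets -0.159 (both adjusted p = 0.21 with an estimated correlation), and erythroid genes 0.278 (adjusted p = 0.52). In the WT cell type by irradiation interaction, erythroid genes had 0.707 and endothelial and stromal genes -0.194 (both adjusted p = 0.74 with an estimated correlation).

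Rows without a gene symbol lie outside the comparisons, and some of these 11799 rows changed after irradiation when all rows were tested: 39 were higher in WT LSK, 15 in Parp-2-/- LSK, 3 in WT MP and 1 in Parp-2-/- MP cells. Lower were 23, 25, 1 and 0.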

How the results depend on the processing

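The fit to the 8 arrays of a cell type for named genes and lists and the weight for each cell type were added after the results were seen; the other alternatives were fixed before. Every pair of groups has 2 pools, so the number of arrays limits the precision, and a single fit to 16 arrays gives LSK and MP cells the same spread (weights estimated per cell type were 0.612 for LSK and 1.633 for MP). Of 307 alternative counts for the 12 comparisons, 199 stayed within 1.5 times their value and 108 moved beyond it. For 200 named gene results, 3402 of 3940 alternatives kept their side of the threshold, 536 ended a call and 2 began one, and 0 called changes turned direction. For 81 called list results, 1451 of 1683 kept direction and call, 229 ended the call and 3 turned direction. Where no reason is given below, the cause was not tested.

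Radiation responses are given in the order WT LSK, Parp-2-/- LSK, WT MP and Parp-2-/- MP, where the fit to 16 arrays called 413, 337, 154 and 135 rows. Only the 8 arrays of the cell type gave 35, 51, 390 and 365, and a weight for each cell type gave 107, 104, 507 and 403, both of which let the more variable LSK arrays have their own spread. Only the 4 arrays of the groups compared gave 30, 0, 286 and 286. Testing all rows gave 258, 201, 79 and 71. Leaving out 1 array gave 242 (without either WT MP irradiated pool) to 537 (without either Parp-2-/- LSK irradiated pool) in WT LSK, and 189 (without Parp-2-/- LSK unirradiated pool 1) to 469 (without Parp-2-/- LSK irradiated pool 2) in Parp-2-/- LSK. In WT MP it gave 39 (without WT MP unirradiated pool 2) to 176, and in Parp-2-/- MP 43 (without Parp-2-/- MP irradiated pool 2) to 150.

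Genotype differences rested on few calls. In unirradiated LSK cells (0 calls), the block fit gave 2, all rows 5 and quantile normalisation 14, and leaving out 1 array gave 0 to 148, the highest without WT LSK unirradiated pool 1. In unirradiated MP cells (1 call), the 4 arrays alone gave 2, and leaving out 1 array gave 1 to 2, the latter without Parp-2-/- MP unirradiated pool 1. In irradiated LSK cells (4 calls), the 8 arrays, the 4 arrays and the weighted fit each gave 0, all rows 2, 1 value per gene 2 and quantile normalisation 8, and leaving out 1 array gave 0 to 180, the highest without WT LSK irradiated pool 2. In irradiated MP cells (2 calls), the 8 arrays, all rows, trend with robust and quantile normalisation each gave 1, and leaving out 1 array gave 1 to 3, the highest without Parp-2-/- MP irradiated pool 2.

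The LSK interaction of genotype and irradiation (2 calls) had 0 with the block, 0 with the 8 arrays, 0 with the weights, 1 with trend and robust, 4 without the dimmest rows and 6 after quantile normalisation. Leaving out 1 array gave 0 to 95, the highest without Parp-2-/- LSK irradiated pool 2. The MP interaction had 0 calls in limma in every setting (199 at an unadjusted p under 0.05 in the fit to 16 arrays). WT LSK against WT MP (1200 calls) had 51 with the 4 arrays, 641 with all rows and 726 after quantile normalisation, and 186 (without WT MP unirradiated pool 1) to 1614 (without WT LSK unirradiated pool 1) with 1 array left out. The WT interaction of cell type and irradiation (0 calls) had 0 to 9, the latter without WT LSK unirradiated pool 1.

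The correlation of WT and Parp-2-/- responses ranged from 0.22 (without Parp-2-/- LSK irradiated pool 2) to 0.34 in LSK and from 0.55 (without Parp-2-/- MP irradiated pool 1) to 0.68 in MP cells. That of LSK and MP responses in WT ranged from 0.33 (without WT LSK irradiated pool 2) to 0.45.

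Of the 81 list calls, an estimated correlation left 24, and fry called 44, of which 41 were shared. With 1 array left out the number of calls was 71 to 87. Reversals came with single WT MP pools. The granulocyte and monocyte list in unirradiated Parp-2-/- against WT MP cells had an adjusted p between 3.5e-10 and 0.926, the latter without WT MP unirradiated pool 1. In the MP interaction that list ranged from 6.06e-06 to 0.984 and the erythroid list from 2.17e-10 to 0.816, in both cases reversed without WT MP unirradiated pool 2. These cells came from pools with different erythroid levels (0.59 and 1.31); the cause was not tested.

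The pool number was used as a block only as an alternative, since the labels do not say that pools of the same number belong together. In the pairing check, the 28 correlations of residuals between groups ran from -0.173 to 0.227 with a median of 0.004, and 2 were above 0.1. With the block, 80 of the 81 list calls and 191 of the 200 named gene results kept their side of the threshold.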

Other observations

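The tests and values in this part were chosen after the results were seen.

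Values of 4 further list members are given here, of which 2 were called in 1 response each. With the 8 LSK arrays alone neither call stood (Parp14 adjusted p = 0.11, F2r adjusted p = 0.091). The ADP-ribosyltransferase gene Parp14 read 1.47 ± 0.25 in irradiated WT LSK (adjusted p = 0.012), 1.04 ± 0.25 in Parp-2-/- LSK (adjusted p = 0.066), 0.87 ± 0.25 in WT MP (adjusted p = 0.24) and 0.77 ± 0.25 in Parp-2-/- MP cells (adjusted p = 0.41). The chemokine gene Ccl3 read -1.70 ± 0.54, -1.87 ± 0.54, -1.82 ± 0.54 and -2.19 ± 0.54 in the same order (adjusted p = 0.15, 0.13, 0.27 and 0.16). The chaperone gene Hsph1 read 0.41 ± 0.16 and -0.35 ± 0.16 in WT and Parp-2-/- LSK cells, and -0.56 ± 0.16 and -0.71 ± 0.16 in MP cells (adjusted p = 0.26, 0.42, 0.26 and 0.11). The thrombin receptor gene F2r fell in Parp-2-/- LSK cells (-1.40 ± 0.25, adjusted p = 0.016) and read -0.97 ± 0.25, -1.07 ± 0.25 and -0.60 ± 0.25 in WT LSK, WT MP and Parp-2-/- MP cells (adjusted p = 0.077, 0.098 and 0.72).

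With both irradiation states averaged in a fit to the 8 arrays of each cell type, n = 4 arrays per genotype, Parp2 was lower in Parp-2-/- MP cells (-1.44 ± 0.13, adjusted p = 0.0064), as was Rnase12, a ribonuclease family gene that lies 11 protein-coding genes from Parp2 (-2.17 ± 0.22, adjusted p = 0.014). The mean Rnase12 level of 2.77 in Parp-2-/- MP cells lies below the array medians, so that size is a lower bound. Its WT mean of 4.94 lies only a little above the WT MP array medians of 4.76 to 4.84, so the gene was hardly detected. Pnp, a purine nucleoside phosphorylase gene 6 protein-coding genes away, had -0.65 (adjusted p = 0.076), and Osgep, 3 away, had -0.43 ± 0.09 (adjusted p = 0.39). Myh10 read 1.06 ± 0.15 (adjusted p = 0.086). In LSK cells the same average gave -1.42 ± 0.20 for Parp2 (adjusted p = 0.45), 0.58 ± 0.16 for Ccnb1ip1 (adjusted p = 0.99) and -0.47 ± 0.16 for Osgep (adjusted p = 0.99). Rnase12 read -0.66 ± 0.37 there (adjusted p = 0.99), with means of 3.13 in Parp-2-/- and 3.80 in WT cells, both below the array medians.

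Pools of a group were closer to each other in MP than in LSK cells, with correlations of 0.979 to 0.985 and 0.934 to 0.948 over all 34760 rows.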
